A study of Mus musculus with 21 samples.

How the data were processed

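The series profiles CGR8 cells, a mouse embryonic stem cell line, before differentiation and as embryoid bodies, the cell aggregates in which stem cells start to form the germ layers. Aggregates were formed in hanging drops of 500 cells per 25 µL and moved to a shaker after day 2, with or without ascorbic acid (vitamin C) at 100 µM. Total RNA (100 ng) was turned into biotinylated cRNA and hybridised to an Affymetrix mouse genome array, which reports each transcript by 1 or more probe sets. There are 21 arrays in 7 groups of 3 biological replicates, as the labels call them. Per the submitters' processing notes, the deposited values are log2 signals made with RMA. This method corrects background, normalises arrays by quantiles and summarises the probes of each probe set. Its version is not given in the sources used here. The submitters also state that samples were taken further only where ascorbic acid had raised the number of beating aggregates later in culture, so the arrays are a selected set.

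The table holds 45101 probe sets on each array, with values from 2.51 to 14.51 and array medians from 6.05 to 6.19. Of these, 34958 carried 1 gene symbol in the platform annotation, 932 carried several and 9211 carried none. AFFX control probe sets numbered 64. Gene names were checked by Entrez identifier against a RefSeq table, which held 34754 of the probe sets with 1 symbol and changed 0 symbols. Each of 18194 genes was represented by its probe set with the highest mean over all arrays, and 9012 genes had over 1 probe set. No genome build is named with the arrays, so no coordinates are given. T (Tbxt) has no probe set under its own name in the annotation and was not analysed here. All 21 value columns were used, and no pair among the 210 pairs of arrays held identical values. Arrays give no read depth; their number limits the precision.

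Gene tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend) on the log2 values, with the 7 groups as means. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all 18194 genes. The comparisons were treated minus control at days 2, 3 and 5, their average, an F test of whether the effect differs between days, and the 3 steps between successive days without ascorbic acid. This unpaired fit, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined.

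Whether the replicate numbers pair the arrays was checked by correlating, over all genes, each array's deviation from its group mean. Treated and control arrays of the same day and number had r of 0.178 to 0.679 in 9 of 9 pairs, above the preset 0.1. Control arrays of the same number on successive days had r of -0.07 to 0.26 and were not treated as paired. A fit with each treated array paired with the control of its day and number (9 pairs as blocks, 18 arrays) was therefore added after seeing the data. It is called the paired fit, and its counts stand beside those of the unpaired fit. A block for the replicate number across all days had been planned and was run as an alternative.

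Gene lists (27, covering lineages, matrix, dioxygenases, hypoxia, stress, metabolism and signalling) were tested with camera at a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry. List p values were adjusted over the lists of a comparison. Counts of called list members are given over all genes and "adjusted over the list alone". Position along normal differentiation was measured by projecting the arrays of a day on the difference between control groups of other days, with an exact two-sided permutation test over 8000 assignments of treatment within days.

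Named genes follow a rule. For each comparison it takes the 10 with the largest rise and the 10 with the largest fall among called genes whose replicates do not overlap between groups. In the paired fit the sign had to be the same in every pair, and for the average on every day. The rule adds up to 4 called members of each list that was called or had at least 3 called members, 11 measured marker genes whatever their test, and the 10 genes with the smallest p for the day difference. Clone names are left out of the rule. Levels of about 4 or lower are not shown to exceed background, so no fold is given against them. Genes outside it are marked as chosen after their values were seen.

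On simulated data with day 5 changes in 50 genes at each size, the unpaired fit found 66% of 1.5-fold, 94% of 2-fold and 100% of 3-fold changes where pairs shared no variance, with 10 false calls among 190. The paired fit found 36%, 90% and 100%, with 15 false calls among 178. Where pairs shared 0.5 of the variance, the unpaired fit found 64%, 92% and 98% with 0 false calls among 177, and the paired fit 80%, 100% and 100% with 13 among 203. At the simulated unchanged day, limma called 0 genes in either fit, and 0 lists were called. The simulated noise was independent between genes, so this does not show how often lists of correlated genes are called without a change. A shift of 0.2 put into the position measure came back as 0.200. It was added along the same axis on which it was read, so this checks the calculation only. Alternatives for each result covered the replicate blocks, array weights, robust and untrended variance, other choices of probe set, a signal filter, renewed scaling, fits of fewer arrays and leaving out each array or pair. Probe sets with several symbols were left out of the gene tests. The 9160 without a symbol, AFFX controls aside, were tested apart.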

Results

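Transcript levels were measured in CGR8 mouse embryonic stem cells at day 0 and in embryoid bodies grown with and without ascorbic acid and collected at days 2, 3 and 5. The 7 groups hold 3 biological replicates each, on 21 arrays. The labels place the question in early differentiation: which genes ascorbic acid changes before beating heart cells appear, in cultures chosen because ascorbic acid later raised the number of beating aggregates. Values are log2 signals, so a difference of 1 is a 2-fold change. Errors of differences are standard errors from limma, with n = 3 per group.

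Day of culture separated the arrays most. The first principal component, with 54.6% of the variance, ran from stem cells and day 2 aggregates to day 5, and the second, with 15.9%, set day 0 apart. Correlations between arrays of a group were 0.966 to 0.995. Day 0 replicate 1 stood apart from the other day 0 arrays, with r of 0.969 and 0.966 against 0.989 between those. It had r of 0.982 with day 2 control replicate 1. Replicate 3 of day 3 lay closer to day 2 in both arms, at -18.3 and -18.9 on the first component against -6.10 to -2.19 for the other day 3 arrays. The 3' minus 5' signal of Actb, a sign of RNA integrity, ran from 0.71 to 1.40, highest in day 2 control replicate 2.

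**Figure D1:**
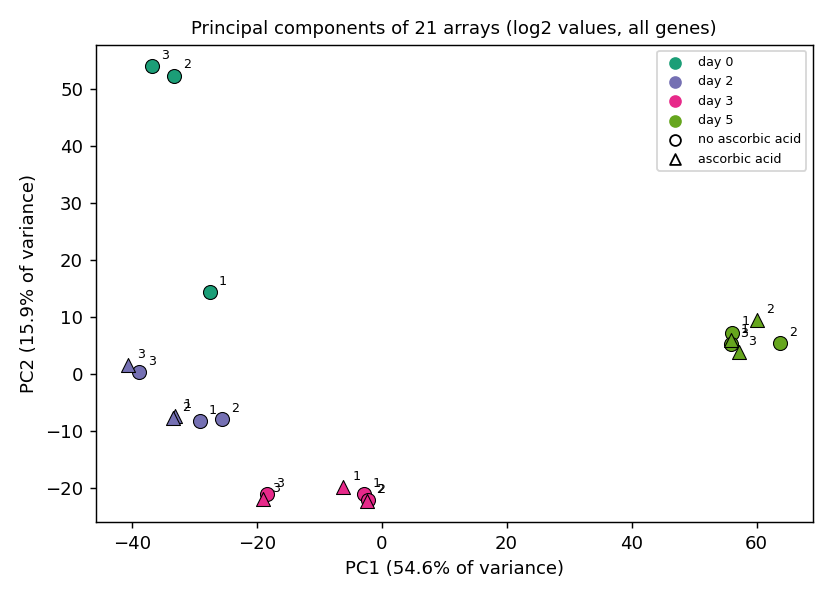
First and second principal components of the 21 arrays over all 18194 genes, 1 point per array, by day and treatment. With 54.6% and 15.9% of the variance on the axes, day 0 replicate 1 lies at 14.3 on the second component, the other day 0 arrays at 52.3 and 54.0.

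From day 0 to day 2 without ascorbic acid, 15 of 18 naive pluripotency genes fell and 7 of 14 genes of the primed epiblast rose (adjusted p = 0.0214 and 0.0861 for the lists with an estimated correlation). Klf4, a transcription factor of the naive state, fell from 10.84 ± 0.75 to 6.54 ± 0.17 (SD, n = 3), which is 19.7-fold, and Tfcp2l1, of the same network, fell 11.7-fold, and Prdm14 fell from 6.83 to 3.92, near the low end of the signals. Fgf5, the classical marker of the primed epiblast, rose 8.24-fold (log2 difference 3.04 ± 0.42), and Pou3f1 rose 9.06-fold. The largest fall was that of Mme, which encodes the membrane peptidase neprilysin (from 8.65 to 4.01, also near the low end), and the largest rise that of the kinase gene Pim2 (9.67-fold). Of 18194 genes, 873 rose and 1271 fell (adjusted p under 0.05, limma).

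Of 18 measured naive pluripotency genes, 15 fell and 0 rose (17 fell adjusted over the list alone; median change -2.28; adjusted p = 6.17e-22, and 0.0214 with an estimated correlation). Of 14 primed epiblast genes, 7 rose, among them Dnmt3a (2.15 ± 0.24), which encodes a DNA methyltransferase, and Zic2 (1.87 ± 0.37). The primed epiblast list had adjusted p = 2.81e-06, and adjusted p = 0.0861 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 16 cases, led by Idi1 (2.83-fold) and Hmgcs1 (1.32 ± 0.18). The cholesterol list had adjusted p = 6.39e-09, and adjusted p = 0.126 with an estimated correlation. Immediate early and heat shock genes fell in 8 of 18 cases, such as Fos (-2.63 ± 0.31) and Egr1 (-2.28 ± 0.33). This list held its call (adjusted p = 7.24e-07, and 0.00624 with an estimated correlation). Dioxygenases that act on chromatin fell in 9 of 23 cases, among them Tet2 (-2.73 ± 0.30) and Tet1 (-1.49 ± 0.23), which oxidise methylated cytosine. The dioxygenase list had adjusted p = 3.05e-06, and adjusted p = 0.0522 with an estimated correlation.

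Hypoxia and HIF target genes fell in 8 of 27 cases between these days, among them the glucose transporter gene Slc2a3 (-1.75 ± 0.23) and the glycolytic gene Pfkp (-2.34 ± 0.40). The HIF list had adjusted p = 1.26e-07, and adjusted p = 0.126 with an estimated correlation. Neuroectoderm genes rose in 5 and fell in 1 of 18 cases (Sox3 1.32 ± 0.28, Sox11 1.24 ± 0.22; adjusted p = 0.0112, and adjusted p = 0.126 with an estimated correlation). In the collagen and matrix list 6 of 21 genes fell, such as Fn1 (-2.18 ± 0.25) and Nid1 (-2.81 ± 0.44). Its median was 0.01 while its test pointed down (adjusted p = 0.0152, and adjusted p = 0.303 with an estimated correlation). General pluripotency genes fell in 2 of 14 cases (Gdf3, Sall4; adjusted p = 0.0301, and adjusted p = 0.519 with an estimated correlation). Amino acid response genes fell in 1 of 22 (Cth; adjusted p = 0.00154, and adjusted p = 0.723 with an estimated correlation). Stem cells and aggregates were kept in different media, so medium and time cannot be separated here. The 3' minus 5' signal of Actb also differed, at 0.79, 0.82 and 0.87 at day 0 and 1.22, 1.40 and 0.94 in day 2 controls. Those of Gapdh and Tfrc overlapped between the groups. RNA quality thus cannot be told apart from this step either. Without day 0 replicate 1, the array that stood apart, the count was 3713, without day 0 replicate 2 it was 1122, without day 0 replicate 3 it was 1420, and without day 2 control replicate 1 it was 1367. A fit of these 6 arrays alone called 198.

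From day 2 to day 3 without ascorbic acid, 7 of 20 genes of the primitive streak and nascent mesoderm rose (adjusted p = 0.457 for the list with an estimated correlation). Eomes, a T-box factor needed for mesoderm and endoderm, rose from 7.73 ± 0.72 to 11.90 ± 0.91 (SD, n = 3), a difference of 4.17 ± 0.43. Fgf8 rose 12.3-fold, Gsc 8.40-fold and Mixl1 7.48-fold, all of them streak genes. Nanog, which had fallen 3.71-fold by day 2, rose 3.83-fold again (1.94 ± 0.35), while Fgf4 (-1.97 ± 0.49) and Nr0b1 (-2.11 ± 0.53) fell. In all, 885 genes rose and 172 fell. After renewed quantile normalisation the split was 574 and 235.

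Of 20 streak and nascent mesoderm genes, 7 rose and 0 fell (10 rose adjusted over the list alone). The median of the streak list was 0.58 (adjusted p = 3.75e-05, and adjusted p = 0.457 with an estimated correlation). Wnt targets rose in 5 of 14 cases, among them Sp5 (3.27 ± 0.84) and Axin2 (1.32 ± 0.27). The Wnt list had adjusted p = 0.00154, and adjusted p = 0.457 with an estimated correlation. Definitive endoderm genes rose in 3 of 14 cases (Gsc, Foxa2 2.72 ± 0.77, Trh 1.45 ± 0.27). The endoderm list had a call that an estimated correlation ended (adjusted p = 0.00357, and adjusted p = 0.541 with an estimated correlation). Germline genes controlled by DNA methylation fell in 2 of 21 cases, Tex19.1 (-1.46 ± 0.36) and Sycp1 (-1.02 ± 0.28). The germline list had adjusted p = 0.00053, and adjusted p = 0.457 with an estimated correlation. Naive pluripotency genes rose in 1 case and fell in 3 of 18 (adjusted p = 0.00392, and adjusted p = 0.714 with an estimated correlation). Cell cycle genes rose in 3 and fell in 1 of 22 (adjusted p = 0.00626, and adjusted p = 0.714 with an estimated correlation). The oxidative stress list, with 1 fall in 19 genes (Gsta4), and the amino acid response list, with 0 of 22 genes changed, had adjusted p = 0.0263 each, and adjusted p = 0.457 and 0.77 with an estimated correlation. The spread among day 3 controls was wide for these genes, with an SD of 2.13 for Mixl1 and 1.99 for Gsc. The count was 258 without day 3 control replicate 2, without day 3 control replicate 1 it was 435 and without day 2 control replicate 3 it was 560. Without day 2 control replicate 1, 612 rose and 105 fell.

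From day 3 to day 5 without ascorbic acid, pluripotency ended and mesoderm derivatives appeared. Pou5f1 fell 35.2-fold (-5.14 ± 0.25) and Nanog 49.6-fold (-5.63 ± 0.35). Snai2, a driver of the epithelial to mesenchymal transition, rose 101-fold, from 4.67 ± 0.05 to 11.33 ± 0.33 (SD, n = 3), and Igf2, a fetal growth factor gene, rose 63.6-fold. Hand2, a factor of the heart fields, rose 28.6-fold. Streak genes that had risen by day 3 fell, such as Eomes (-4.73 ± 0.43) and Fgf8 (-4.17 ± 0.36). A total of 1652 genes rose and 1681 fell. Without day 3 control replicate 3 these were 1144 and 1080.

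Cardiac mesoderm and progenitor genes rose in 14 of 20 cases and fell in 0, among them Foxf1 (4.03 ± 0.33) and Pdgfra (3.72 ± 0.42). That list had a median of 1.49 and adjusted p = 1.22e-14, and 0.00171 with an estimated correlation. General pluripotency genes fell in 11 of 14 cases (adjusted p = 1.22e-14, and 0.00443 with an estimated correlation). Primed epiblast genes fell in 11 of 14 (adjusted p = 2.49e-08, and 0.0213 with an estimated correlation). Collagens and matrix rose in 11 of 21 cases (Vcan 2.75 ± 0.27, Col3a1 2.27 ± 0.53; adjusted p = 1.03e-09, and 0.00581 with an estimated correlation). The enzymes and chaperones that hydroxylate and crosslink collagen rose in 10 of 18 cases, among them Serpinh1 (2.15 ± 0.27) and P4ha1 (1.85 ± 0.28). Their list had adjusted p = 4.77e-07, and 0.00443 with an estimated correlation. Blood and endothelial genes rose in 9 of 21 cases, including the embryonic globin gene Hbb-bh1 (4.04 ± 0.59), the receptor gene Kdr (2.73 ± 0.21) and Tal1 (2.43 ± 0.15). The blood list had adjusted p = 4.94e-08, and adjusted p = 0.0641 with an estimated correlation.

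Markers of other cell types rose in the same interval. Extraembryonic endoderm genes rose in 10 and fell in 1 of 18 cases (Gata6 2.79 ± 0.24; adjusted p = 7.84e-06, and 0.0299 with an estimated correlation). Trophoblast genes rose in 6 of 15 (Plac1 4.04 ± 0.28, Cdx2 2.70 ± 0.32; adjusted p = 4.11e-05, and 0.0385 with an estimated correlation). Fibroblast genes rose in 7 of 15 (Vim 2.75 ± 0.25; adjusted p = 3.56e-05, and 0.00581 with an estimated correlation). Germline genes fell in 6 of 21 cases, among them Ddx4 (-4.39 ± 0.27), a germ cell helicase gene (adjusted p = 0.000112, and adjusted p = 0.185 with an estimated correlation). Cell cycle genes rose in 1 and fell in 8 of 22 (Ccne1 -1.31 ± 0.13; adjusted p = 0.00136, and adjusted p = 0.364 with an estimated correlation). BMP and TGF-beta targets rose in 8 and fell in 5 of 16 cases (adjusted p = 0.0481, and adjusted p = 0.249 with an estimated correlation). Naive pluripotency genes rose in 2 and fell in 5 of 18 (adjusted p = 0.0433, and adjusted p = 0.575 with an estimated correlation), among the risers Tbx3 (2.58 ± 0.46). Definitive endoderm genes rose in 6 and fell in 3 of 14 (adjusted p = 0.0407, and adjusted p = 0.491 with an estimated correlation). In the cholesterol synthesis list 1 of 16 genes rose, Stard4 (adjusted p = 0.00876, and adjusted p = 0.491 with an estimated correlation). Cardiomyocyte structure genes rose in 5 and fell in 1 of 22 cases (Tnni1 2.48 ± 0.28, Tnnc1 2.37 ± 0.16), without a call of the list (adjusted p = 0.117).

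Marker genes fixed for all groups were read whatever their test. Pou5f1 stood at 11.76 ± 0.45 at day 0, 11.65 ± 0.06 in day 3 controls and 6.51 ± 0.29 in day 5 controls (SD, n = 3), and at 11.48 ± 0.05 and 6.57 ± 0.72 with ascorbic acid at days 3 and 5. The mesoderm factor gene Mesp1 reached 7.73 ± 0.68 in day 3 controls and 7.85 ± 0.92 in treated aggregates. Nkx2-5, an early cardiac factor gene, had means between 7.37 and 7.78 in the control groups and between 7.42 and 7.66 in treated groups. The means of the troponin gene Tnnt2 lay between 5.40 and 5.62 in all 7 groups. The cardiac myosin gene Myh6 was at 4.57 ± 0.45 in day 5 controls and 5.55 ± 1.39 in treated aggregates. Its difference averaged over days was 0.61 ± 0.14 in the paired fit (adjusted p = 0.0311, limma), higher in 8 of 9 pairs, and was not called in the unpaired fit (adjusted p = 0.998). Day 2 controls stood higher than day 5 controls for this Myh6 probe set, at 6.33 ± 0.16. Another Myh6 probe set, near the low end of the signals (mean 3.19), read 0.06, 0.08 and -0.12 at days 2, 3 and 5. The endoderm factor gene Sox17 rose from day 3 to day 5 (3.35-fold; adjusted p = 4.34e-07). Sox1 and Afp did not pass the test in any comparison. The collagen gene Col1a1 was at 7.71 in day 5 controls and 8.27 in treated aggregates, which did not pass the test.

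**Figure D2:**
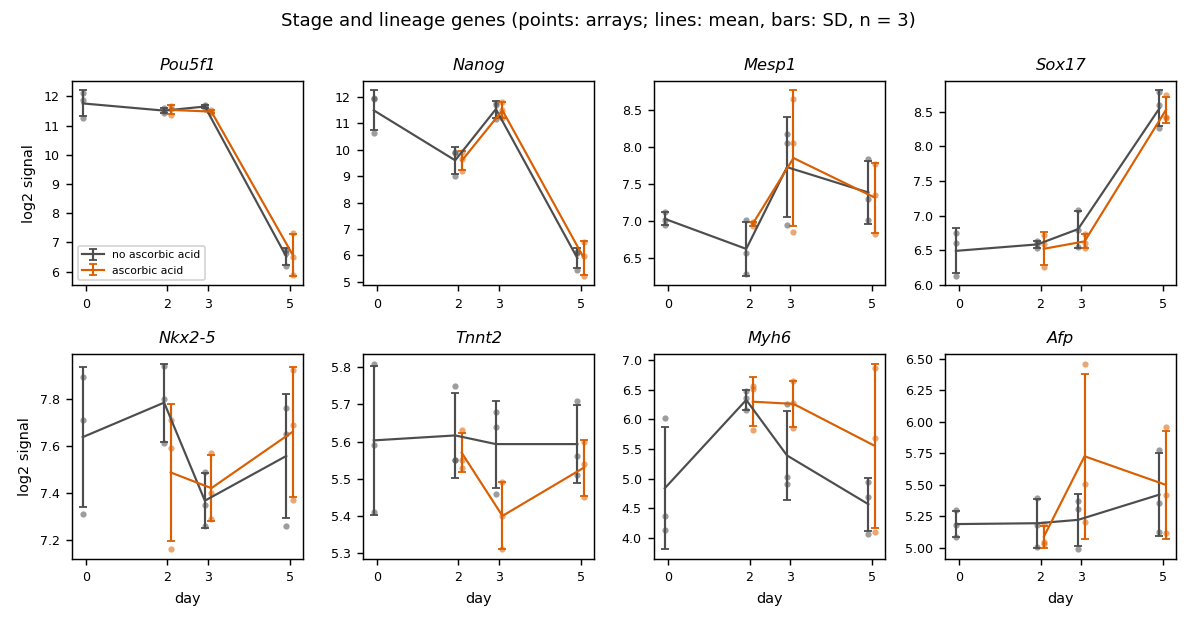
Log2 signal of 8 marker genes by day, 1 point per array, with means and SD of 3 replicates for control and treated groups. The means of Pou5f1 and Nanog end at 6.51 and 5.90 in day 5 controls and at 6.57 and 5.90 in treated aggregates. Group means of Nkx2-5 and Tnnt2 stay within 7.37 to 7.78 and 5.40 to 5.62.

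Whether ascorbic acid moved aggregates along differences between control groups of other days was asked with the position measure, in units of the distance between those 2 groups. Day 2 arrays were read on the difference between day 5 and day 3 controls. Day 3 arrays were read on day 5 against day 2, and day 5 arrays on day 3 against day 2. The measure therefore does not read a day 5 advance or delay along the step from day 3 to day 5. Treated minus control was -0.0378 averaged over days (exact permutation p = 0.355, two-sided, 8000 assignments; treated ahead in 2 of 9 pairs), and thus not distinguishable from 0. It was -0.0445 at day 2, -0.0137 at day 3 and -0.0552 at day 5, with exact permutation p of 0.3, 0.8 and 0.7 where the smallest possible is 0.1. The control groups themselves stood at -0.0793, 0.286 and 1.22 on their axes.

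With ascorbic acid at day 2, 10 of 27 hypoxia and HIF target genes and 3 of 18 immediate early and heat shock genes were lower within pairs, and 3 of 19 oxidative stress and 6 of 21 germline genes higher. With an estimated correlation these lists had adjusted p = 0.15, 0.223, 0.0455 and 0.185 in the paired fit. Pttg1, which encodes securin, a regulator of sister chromatid separation, was 2.34-fold higher (10.54 ± 0.22 to 11.77 ± 0.11, SD, n = 3). Hspa1b, an inducible Hsp70 gene, was 2.66-fold lower, and Egln3, a HIF prolyl hydroxylase gene that is itself a HIF target, 2.08-fold lower. Nqo1, a quinone reductase gene of the oxidative stress response, was 2.18-fold higher, and Hormad1, a meiotic chromosome gene, was higher too, from controls at 3.99, 3.50 and 5.62, 2 of them near the low end of the signals. These genes were called in the paired fit, which called 481 genes (383 higher, 98 lower; 232 and 145 after renewed quantile normalisation).

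The unpaired fit called 1 gene at day 2, AI662270 (0.93 ± 0.13, adjusted p = 0.0167), a transcript known by a clone name and given here after its value was seen because the count is small. At an unadjusted p under 0.05 limma gave 1341 genes, or 7.37% of those tested, where chance alone gives a share of 0.05. Pttg1 and Nqo1 had adjusted p = 0.164 and 0.479 in that fit. Other genes that rose in the paired fit were Mymx (1.66 ± 0.22), which encodes a myoblast fusion peptide, the germ cell and sex determination gene Dmrt1 (1.14 ± 0.12), Wt1 (1.14 ± 0.19) and Myl9 (1.15 ± 0.14). Meioc (-1.18 ± 0.14), Irs4 (-1.15 ± 0.13) and the paternally expressed Peg3 (-0.87 ± 0.15) fell. Dpys rose on its brightest probe set (1.42 ± 0.12), while its other probe sets read -0.04 and -0.22. Paired counts depended on the pair: 89 without day 2 replicate 1, 209 without day 2 replicate 2 and 1212 without day 2 replicate 3. The unpaired count was 0 (limma) without day 2 control replicate 1 or 2 or day 2 AA replicate 2, and 8 without day 2 control replicate 3.

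Of 27 hypoxia and HIF target genes, 10 fell and 0 rose in the paired fit (10 adjusted over the list alone; 0 and 3 in the unpaired fit), among them Egln3 (-1.05 ± 0.15), Pfkl (-0.93 ± 0.10), Bnip3 (-0.79 ± 0.16) and Slc2a1 (-0.67 ± 0.13). The list's adjusted p was 3.29e-05 in the unpaired and 6.35e-10 in the paired fit, and adjusted p = 0.596 and 0.15 with an estimated correlation. Its mean was lower in 3 of 3 pairs. Other probe sets of Pfkl read -0.20 and -0.12 and did not pass the paired test. Of 19 oxidative stress genes, 3 rose in the paired fit (13 adjusted over the list alone; 0 and 3 in the unpaired fit), namely Nqo1 (1.12 ± 0.12), Gsr (0.52 ± 0.11) and the ferritin gene Fth1 (0.30 ± 0.06). That list had unpaired adjusted p = 2.02e-05, and 0.0473 with an estimated correlation, and was higher in 3 of 3 pairs. Of 21 germline genes controlled by methylation, 6 rose and 1 fell in the paired fit (7 and 1 adjusted over the list alone). In the unpaired fit 0 passed over all genes and 1 rose adjusted over the list alone. The paired fit had Hormad1, Slc25a31 (1.04 ± 0.14), Tex19.1 (0.99 ± 0.19) and Sohlh2 (0.75 ± 0.12) higher. For the germline list the unpaired adjusted p was 0.0273, and adjusted p = 0.596 with an estimated correlation. The 3' minus 5' signals of Actb (-0.31, -0.32 and -0.03) and Gapdh (-0.21, -0.42 and -0.06) were lower in the treated array of 3 of 3 pairs of this day. Those of Tfrc went both ways (0.31, -0.67 and -0.18).

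Immediate early and heat shock genes fell in 3 of 18 cases in the paired fit (Hspa1b -1.41 ± 0.13, Hspa1a -0.86 ± 0.14, Fos -0.45 ± 0.12). There the list had adjusted p = 0.0173, and adjusted p = 0.223 with an estimated correlation. In the unpaired fit 0 of its genes were called (adjusted p = 0.283). Cholesterol synthesis genes rose in 2 of 16 cases in the paired fit (Insig1 0.59 ± 0.10, Hmgcs1 0.27 ± 0.06), or 9 adjusted over the list alone. Unpaired, their list had adjusted p = 0.000643, and adjusted p = 0.596 with an estimated correlation. Cell cycle genes rose in 3 of 22 in the paired fit (Ccnb2, Cdc6, Pcna; list adjusted p = 0.00136, and adjusted p = 0.311 with an estimated correlation). Neuroectoderm genes fell in 2 of 18 in the paired fit (Fabp7, Nes; list adjusted p = 0.00581, and adjusted p = 0.15 with an estimated correlation). The unpaired fit called these lists too (adjusted p = 0.00604 and 0.0276, and adjusted p = 0.596 and 0.591 with an estimated correlation). The cardiac mesoderm list was called down with 0 of 20 genes changed (unpaired adjusted p = 0.0359, and adjusted p = 0.596 with an estimated correlation). In the paired fit alone the trophoblast list (1 of 15 fell, Krt8) and the vitamin C transport list (2 of 10 fell, Slc2a1 and Slc2a3, both also HIF targets) were called. Each had adjusted p = 0.0451, and adjusted p = 0.223 and 0.327 with an estimated correlation. Tet1 was higher in the paired fit (0.54, adjusted p = 0.0281) and not called in the unpaired fit.

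At day 3, Pttg1 was again higher with ascorbic acid (1.13 ± 0.08, 2.19-fold) and the neural factor gene Zic1 lower (-1.25 ± 0.17), within pairs. The treated arrays of Zic1 lay at 3.88 to 4.17, near the low end of the signals, so this size is uncertain. Twist1, a mesenchymal transcription factor gene, was 2.49-fold lower and the homeobox gene Mkx 2.16-fold lower. Lpl, the lipoprotein lipase gene, was 1.82-fold higher, and Acta2, smooth muscle actin, 1.73-fold higher, while its other, dimmer probe sets read 0.02 and 0.05. The glycolytic genes Pgk1 (-0.63 ± 0.08), Pfkl (-0.61 ± 0.10) and Aldoa (-0.48 ± 0.07) fell. Other probe sets of Pfkl read -0.18 and -0.11 and did not pass the paired test. The paired fit called 36 genes, 17 higher and 19 lower. The unpaired fit called 0 with limma, with a smallest adjusted p of 0.393. At an unadjusted p under 0.05 it gave 269 genes, or 1.48% of those tested, fewer than chance alone would give. Left-out pairs gave 8 without day 3 replicate 1, 6 without day 3 replicate 2 and 14 without day 3 replicate 3. The unpaired count was 1 without day 3 AA replicate 3.

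Hypoxia and HIF target genes fell in 6 of 27 cases at day 3 in the paired fit (10 adjusted over the list alone; 0 and 1 in the unpaired fit). Their median was -0.16, with adjusted p = 3.77e-09 in the unpaired fit, and adjusted p = 0.33 with an estimated correlation (0.0575 paired). Cholesterol synthesis genes were above 0 in 16 of 16 cases, with a median of 0.31. Over all genes 0 passed in either fit, and adjusted over the list alone 11 passed in the paired fit. As a list they had adjusted p = 3.77e-09, and adjusted p = 0.33 with an estimated correlation (0.0317 paired). The paired fit also called the streak list down (0 of 20 genes changed; adjusted p = 1.2e-05, and adjusted p = 0.177 with an estimated correlation). It called p53 targets down with 0 changed genes (adjusted p = 0.000667, and adjusted p = 0.278 with an estimated correlation). Oxidative stress was called up and immediate early and heat shock down, with 0 changed genes. Both had adjusted p = 0.00494, and adjusted p = 0.177 and 0.207 with an estimated correlation. The amino acid response list was called up (adjusted p = 0.00646, and adjusted p = 0.46 with an estimated correlation) and the cardiac mesoderm list down (adjusted p = 0.0314, and adjusted p = 0.278 with an estimated correlation), also with 0 changed genes.

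At day 5, blood and endothelial genes were higher with ascorbic acid. Tal1, the master regulator of the blood lineage, rose from 7.95 ± 0.44 in controls to 9.58 ± 0.08 in treated aggregates (SD, n = 3), which is 3.10-fold (adjusted p = 1.61e-05, limma, unpaired). Gata1, the erythroid factor gene, rose 1.96-fold (0.97 ± 0.14, adjusted p = 0.00778), and Nfe2, another erythroid factor gene, 2.12-fold (1.09 ± 0.20, adjusted p = 0.04). Without day 5 AA replicate 1 neither Gata1 nor Nfe2 was called (adjusted p = 0.0968 and 0.229), and Nfe2 was not called without day 5 AA replicate 2 (adjusted p = 0.383) or day 5 control replicate 2 or 3 (adjusted p = 0.107 and 0.187). Within pairs the embryonic globin gene Hbb-bh1 rose 6.76-fold (2.76 ± 0.24, with 2.86 and 3.31 on its other probe sets). The endothelial receptor gene Tek rose 3.51-fold and Myb 3.02-fold. Hba-x rose in the paired fit as well, but its pairs read 3.14, 1.87 and 0.08. It was not called without day 5 replicate 1 (0.98, adjusted p = 0.283) or day 5 replicate 2 (1.61, adjusted p = 0.145), and read 2.51 without day 5 replicate 3. Zic1 fell from 5.43 ± 0.96 to 3.61 ± 0.34. Its treated arrays lay at 3.34 to 3.99, near the low end of the signals and close to day 0 (3.61 to 4.13), so no fold is given.

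The unpaired fit called 11 genes at day 5, 8 higher and 3 lower. The paired fit called 174, 142 higher and 32 lower, with all 11 among them, and the planned block for replicate number gave 19. Besides those above, the 11 include Hapln1 (1.39 ± 0.21), a link protein of the hyaluronan matrix, Pttg1 (1.36 ± 0.23), Wnk4 (1.16 ± 0.19), the plexin gene Plxnc1 (1.10 ± 0.16) and Cnrip1 (0.84 ± 0.15). Lower were Rps4l (-0.82 ± 0.13) and the homeobox gene Hoxc4 (-0.79 ± 0.15). Other, dimmer probe sets of Plxnc1 read 0.13, -0.10, -0.04, 0.74 and 0.25, and another of Cnrip1 read 0.18. Other rises in the paired fit were those of the atrial myosin gene Myl7 (1.72 ± 0.24), Pyy (1.70 ± 0.30), Pygl (1.65 ± 0.22), Slc18a2 (1.55 ± 0.18) and Col5a2 (1.45 ± 0.20). Falls in the paired fit included the meiotic gene Sycp3 (-0.97 ± 0.21), Fgf5 (-0.77 ± 0.11) and Hoxd8 (-0.74 ± 0.14). Another probe set of Fgf5 read -0.24 and another of Hoxd8 -0.40, and neither passed the paired test. Sycp3 was not called without day 5 replicate 1, 2 or 3 (adjusted p up to 0.268, without replicate 3), nor Hoxd8 without day 5 replicate 1 or 2 (adjusted p = 0.102 and 0.154). The unpaired count was 1 without day 5 AA replicate 1, 3 without day 5 AA replicate 2 and 54 without day 5 AA replicate 3. Without day 5 control replicate 2 it was 10 higher and 1 lower, and without day 5 control replicate 3 it was 6 higher and 9 lower. The paired count was 56 without day 5 replicate 1 and 96 without day 5 replicate 2, and without day 5 replicate 3 it was 123 higher and 61 lower.

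Of 21 blood and endothelial genes, 21 lay above 0 with a median of 0.97. In the unpaired fit 2 rose (16 adjusted over the list alone) and in the paired fit 12 rose (18 adjusted over the list alone), while 0 fell in either. The list had adjusted p = 5.22e-39, and 0.000858 with an estimated correlation, and was higher in 3 of 3 pairs. Cardiomyocyte structure genes rose in 3 of 22 cases in the paired fit (Myl7, Actc1 1.26 ± 0.25, Ryr2 0.67 ± 0.15; 6 adjusted over the list alone) and in 0 in the unpaired fit. The cardiomyocyte list had unpaired adjusted p = 0.00091, and adjusted p = 0.72 with an estimated correlation. Its pairs read 0.515, 0.414 and 0.0109, so the third pair showed almost no change. Actc1 and Ryr2 were not called without day 5 replicate 1 (adjusted p = 0.407 and 0.517) or day 5 replicate 2 (adjusted p = 0.181 and 0.324). Hypoxia and HIF targets, lower at days 2 and 3, were called up at day 5. In the paired fit 2 of 27 rose, Ankrd37 (0.85 ± 0.16) and Higd1a (0.56 ± 0.09; list adjusted p = 6.54e-06, and adjusted p = 0.177 with an estimated correlation). The unpaired fit gave adjusted p = 0.00796, and adjusted p = 0.72 with an estimated correlation. Ankrd37 and Higd1a were not called without day 5 replicate 1 (adjusted p = 0.129 and 0.115), nor Ankrd37 without day 5 replicate 2 (adjusted p = 0.181). Other probe sets of Higd1a read 0.14 and -0.15, the second near the low end of the signals (mean 3.78). The amino acid response list was called up with 1 riser of 22 in the paired fit (Cth; list adjusted p = 1.71e-08, and adjusted p = 0.177 with an estimated correlation), and in the unpaired fit (adjusted p = 0.0227, and adjusted p = 0.825 with an estimated correlation). The second pair carried most of it (0.109, 0.526 and 0.0573), and Cth was not called without day 5 replicate 2 or 3 (adjusted p = 0.265 and 0.129).

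Some lists were called at day 5 in the paired fit alone. General pluripotency was lower with 0 of 14 genes changed (adjusted p = 0.00271, and adjusted p = 0.313 with an estimated correlation), and naive pluripotency with 0 of 18 (adjusted p = 0.012, and adjusted p = 0.346 with an estimated correlation). BMP and TGF-beta targets were lower with 1 of 16 fallen (Msx1; adjusted p = 0.00373, and adjusted p = 0.231 with an estimated correlation). Trophoblast was lower as a list, although its 1 called gene of 15, Ets2, rose (adjusted p = 0.012, and adjusted p = 0.177 with an estimated correlation). The oxidative stress list was called up (1 of 19 rose, Gclm; adjusted p = 0.00719, and adjusted p = 0.177 with an estimated correlation).

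**Figure D3:**
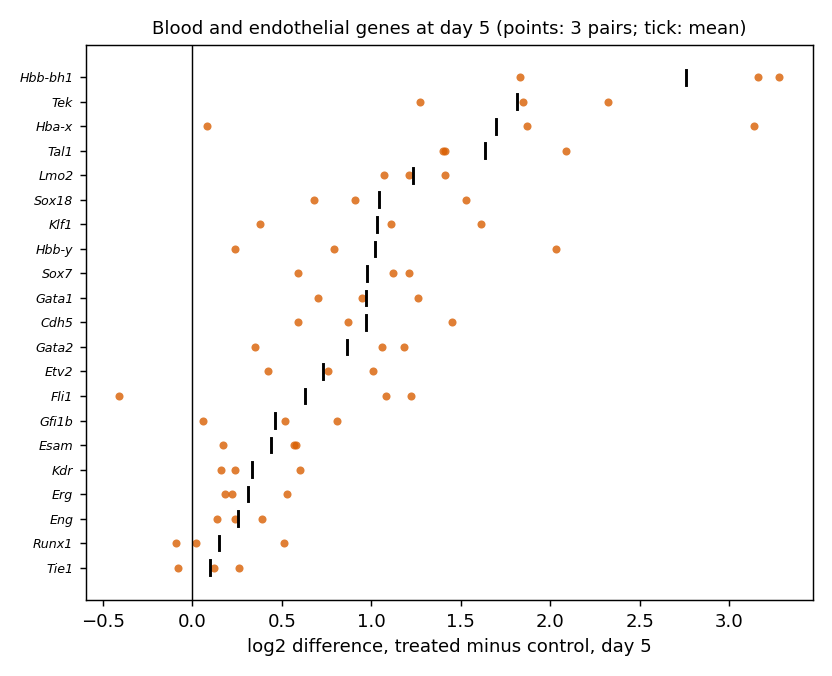
Treated minus control log2 difference at day 5 for each blood and endothelial gene, with the 3 pairs of arrays as points and their mean. All 21 means lie above 0, with a median of 0.97 and the largest, Hbb-bh1, at 2.76.

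**Figure D4:**
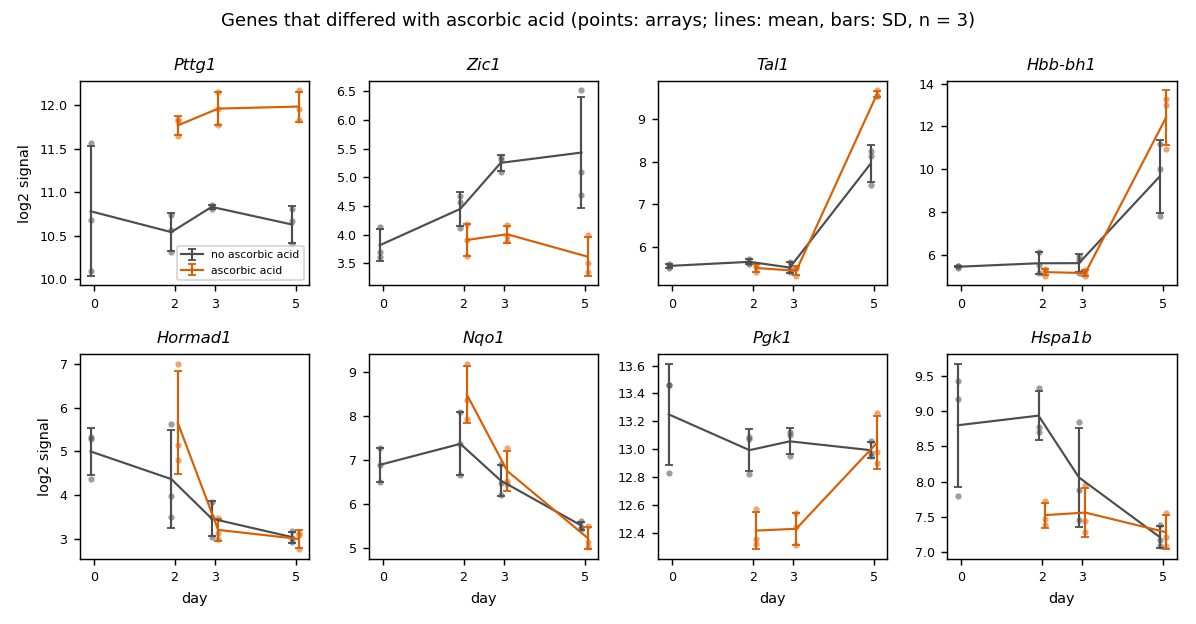
Log2 signal of 8 genes by day with and without ascorbic acid, 1 point per array, with lines for the means and bars for the SD of 3 replicates. Pttg1 is higher with ascorbic acid in 9 of 9 pairs, and Tal1 and Hbb-bh1 are higher in all 3 pairs of day 5.

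Averaged over days 2, 3 and 5, ascorbic acid raised Pttg1 (1.24 ± 0.13, adjusted p = 0.000236, higher in 9 of 9 pairs), Lpl (0.78, adjusted p = 0.042, 9 of 9 pairs) and Helz2 (0.76, adjusted p = 0.024, 8 of 9 pairs). All 3 probe sets of Pttg1 lay above 0 on each day. Another probe set of Lpl read 0.42, 0.49 and -0.04 at days 2, 3 and 5. Ascorbic acid lowered Zic1 (-1.20, of uncertain size since its treated arrays lie near the low end of the signals; adjusted p = 0.013, 9 of 9 pairs) and Twist1 (-0.91, adjusted p = 0.0293, 8 of 9 pairs). These 5 genes were all that the unpaired fit called. The planned replicate block gave 12 and the paired fit 353, 263 higher and 90 lower, with these 5 among them. In the paired fit Mkx fell (-1.05 ± 0.07, 9 of 9 pairs). As3mt (1.01 ± 0.14), Gask1b (0.93 ± 0.09), the splicing factor gene Mbnl1 (0.92 ± 0.09) and Plac8 (0.91 ± 0.09) rose. Other probe sets of Mbnl1 did not follow it, at 0.06, 0.09 and 0.02, and -0.08, -0.02 and 0.11 at days 2, 3 and 5. Another of Gask1b read 0.01, 0.31 and 0.84. Smooth muscle genes rose in 3 cases and fell in 1 (Acta2 0.73 ± 0.08, Myl9 0.61 ± 0.08, Tagln 0.42 ± 0.09, Tpm2 -0.24 ± 0.06), and Col5a2 (0.70 ± 0.12), Col1a2 (0.58 ± 0.08) and Fn1 (0.21 ± 0.05) rose.

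On average over days, the blood and endothelium list was called up (adjusted p = 1.41e-10, and adjusted p = 0.103 with an estimated correlation, or 0.00655 paired). Its mean lay above 0 in 5 of 9 pairs, 3 of them at day 5, and was -0.07, 0.02 and 0.92 at days 2, 3 and 5. Cholesterol synthesis genes rose in 4 of 16 cases in the paired fit (unpaired list adjusted p = 8.71e-07, and adjusted p = 0.342 with an estimated correlation, or 0.0373 paired). Oxidative stress genes rose in 5 of 19 in the paired fit and were higher as a list in 9 of 9 pairs (unpaired list adjusted p = 1.01e-06, and 0.0273 with an estimated correlation, or 0.0147 paired). Hypoxia and HIF targets fell in 8 of 27 in the paired fit (unpaired list adjusted p = 0.000323, and adjusted p = 0.43 with an estimated correlation). Neuroectoderm was called down with 1 of 18 fallen, Zic1 (adjusted p = 0.00586, and adjusted p = 0.174 with an estimated correlation). Cell cycle was called up (3 of 22 rose in the paired fit; list adjusted p = 0.00169, and adjusted p = 0.236 with an estimated correlation). Unpaired, its adjusted p was 0.00643, and adjusted p = 0.585 with an estimated correlation. The streak list was called down (1 of 20 fell in the paired fit, Eomes; unpaired list adjusted p = 0.012, and adjusted p = 0.585 with an estimated correlation). So was trophoblast (1 rose and 1 fell of 15 in the paired fit; unpaired list adjusted p = 0.0349, and adjusted p = 0.43 with an estimated correlation). The collagen hydroxylation and chromatin dioxygenase lists, which hold enzymes that use ascorbic acid as a cofactor, had 0 of 18 and 0 of 23 genes changed in either fit on average over days. The unpaired count of 5 was 1 without day 2 control replicate 1, day 2 AA replicate 2, day 3 control replicate 1 or day 5 AA replicate 2. It was 3 without day 2 AA replicate 1 or 3, day 3 AA replicate 1, 2 or 3, day 3 control replicate 2 or day 5 control replicate 1 or 2. Higher counts were 9 without replicate 3 of the day 2 or day 3 controls, 10 without day 5 control replicate 3 and 12 without day 5 AA replicate 3. The paired count was 189 without day 3 replicate 1, 195 without day 3 replicate 2, 208 without day 3 replicate 3, 215 without day 2 replicate 1, 216 without day 5 replicate 1 and 648 without day 2 replicate 3.

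Some genes were called on more than 1 day in the paired fit, which estimates 1 variance per gene for all days, so calls on different days are not independent and no p is given for their number. At both days 2 and 3, 23 genes were called, 10 higher and 13 lower on both. Days 2 and 5 shared 20 genes, 14 higher and 2 lower on both and 4 in opposite directions, and days 3 and 5 shared 11, 9 higher and 2 lower. The 6 genes called on all 3 days were Pttg1, Lpl, Acta2, Gask1b and Gstp1, higher on each day, and Mkx, lower on each day. These calls hold for the brightest probe set of each gene. At days 2, 3 and 5 another probe set of Lpl read 0.42, 0.49 and -0.04, and another of Gask1b 0.01, 0.31 and 0.84. The dim probe sets of Acta2 read -0.03, 0.02 and -0.09, and -0.07, 0.05 and 0.19.

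**Figure D5:**
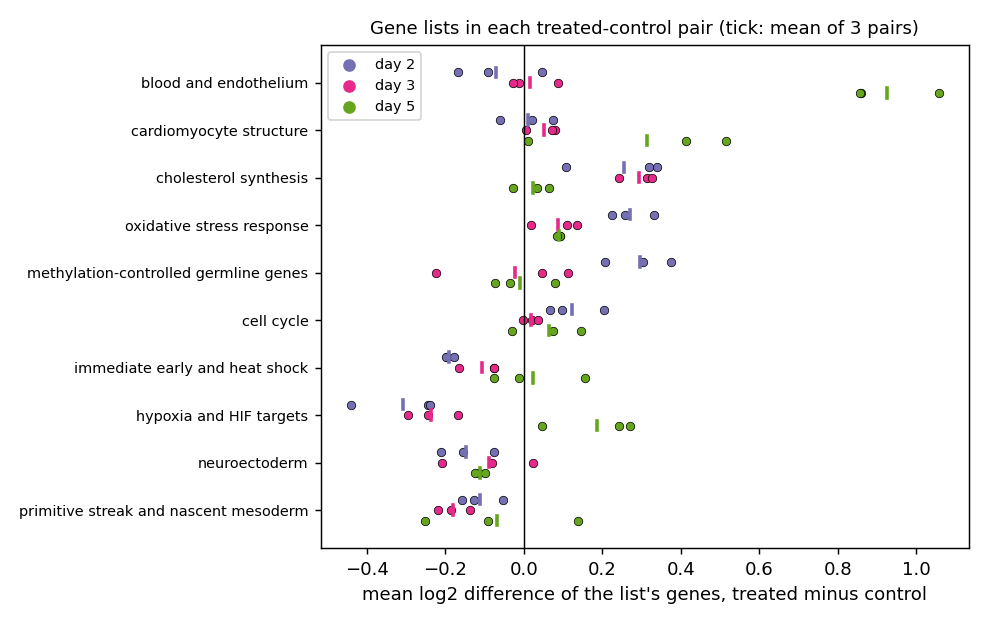
Treated minus control log2 difference of gene lists at days 2, 3 and 5, 1 point per pair of arrays, as means over the genes of a list. Hypoxia and HIF targets lie below 0 in all 6 pairs of days 2 and 3 and above 0 in all 3 pairs of day 5.

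Whether the effect of ascorbic acid differed between days was tested directly. Tal1 was the 1 gene called by the unpaired fit (adjusted p = 0.000811), with differences of -0.14, -0.08 and 1.63 (± 0.15 each) at days 2, 3 and 5. Gata1 and Plxnc1 came next with adjusted p = 0.0881 and 0.103. At an unadjusted p under 0.05 there were 492 genes, or 2.70% of those tested, fewer than chance alone would give. The paired fit called 93 genes. Differences of Hbb-bh1 were -0.41, -0.46 and 2.76 at days 2, 3 and 5, those of Hapln1 0.05, 0.15 and 1.39, and those of the Wnt amplifier gene Rspo3 -0.06, -0.54 and 1.21. Nqo1 read 1.12, 0.22 and -0.29, and Hspa1b -1.41, -0.50 and 0.07. Hormad1 was called as well, but all its arrays of days 3 and 5 lay at 2.77 to 3.85, near the low end of the signals, so its differences are not given. Hmgn3 (-0.86, -0.13 and 0.81) and Dcaf12l1 (-0.74, -0.22 and 0.76) were lower at day 2 and higher at day 5. Paired counts were 37 without day 5 replicate 1, 40 without day 2 replicate 1, 50 without day 3 replicate 1 and 182 without day 2 replicate 3, and unpaired counts 2 without day 2 AA replicate 3 or day 3 AA replicate 1 and 11 without day 5 AA replicate 3. In 30 comparisons of list means between days, 0 passed adjustment (exact permutation). The assignments exchange arrays freely within a day and so leave the pairing out. With 400 assignments the smallest possible p is 0.005, so adjustment over 30 comparisons leaves little room to pass and the result does not show that the lists acted alike. That smallest p was reached (adjusted 0.075) for hypoxia and HIF targets at day 5 against day 2 and against day 3. For blood and endothelium the permutation p was 0.01 (adjusted 0.1) at day 5 against day 2 and 0.075 (adjusted 0.5625) against day 3.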

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

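Chosen only after the results were seen were the paired fit, the tests of RNA quality and of single pairs, the stress list as a sign of handling, and the tests of equal action on every day. The splits of the arrays, the matched gene sets, the signal-matched lists and the lag test were planned.

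The genes named next stand here because an effect of ascorbic acid differed between days by a direct test. The lists further below passed no such test after adjustment. Probe sets without a symbol stand here because no comparison used them. In the unpaired fit this was Tal1 (adjusted p = 0.000811). The paired fit gave 93 genes, and those with the smallest adjusted p were Hbb-bh1 (0.000433), Tal1 (0.000516), Hapln1 (0.00207), Hmgn3 and Nqo1 (0.00234 each), and Rspo3, Hormad1, Hspa1b, Inka1 and Dcaf12l1 (0.00255 each). Of 100 splits within days, 15 gave as many genes as the unpaired fit (real 1, highest other 4). Of 100 exchanges within pairs, 6 gave as many as the paired fit (real 93, highest other 374), so chance is not excluded for either count. Exchanging all pairs of a day turns an effect shared by the days into a difference between them.

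For the effect averaged over days, 1 of 100 splits gave as many genes as the unpaired fit (real 5, highest other 2). In the paired fit, 1 of 100 exchanges gave as many (real 353, highest other 131). That 1 is the real labelling in both cases, the smallest share possible, so chance is unlikely for these counts but not excluded. Within single days and steps the splits are too few for a share under 0.05. Counts of splits reaching the real value, of 10, were 3 at day 2 (real 1, highest other 1), 10 at day 3 (real 0, highest other 1), 3 at day 5 (real 11, highest other 38), 1 from day 0 to day 2 (real 2144, highest other 1306), 1 from day 2 to day 3 (real 1057, highest other 0) and 1 from day 3 to day 5 (real 3333, highest other 0). The day 5 splits with 38 and 14 genes keep some pairs together, while the splits that part all 3 pairs gave 0 apart from the real one. The 1306 came from the split that puts day 0 replicate 1 with day 2 control replicates 1 and 2, and points to the place of that array. Of 4 exchanges within the pairs of a day, 1 reached the real count at day 2 (real 481, highest other 4), at day 3 (real 36, highest other 0) and at day 5 (real 174, highest other 3).

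Blood and endothelial genes were higher with ascorbic acid at day 5, with a median of 0.97. An advance that lifts all genes according to their rise from day 3 to day 5 is argued against. In 10000 sets of other genes matched on that rise in treated arrays, the middle median was 0.0233 and the highest 0.36. The sets were not matched on when genes rise, so an advance shown only by genes that rise late in this interval stays open. A difference in RNA quality is argued against by the 3' minus 5' signal of Actb, whose treated minus control difference averaged 0.07 and ran from -0.23 to 0.24 over the pairs. A single odd pair is argued against by the lowest of the 3 pairs, at 0.857, against a highest of 0.0876 among the pairs of days 2 and 3. A larger share of blood precursors and a higher level per cell also stay open, and these arrays cannot separate them. An action of ascorbic acid on that lineage remains a hypothesis.

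Hypoxia and HIF targets were lower as a list with ascorbic acid at days 2 and 3 and higher at day 5, with 10, 6 and 2 of 27 genes called in the paired fit. These list calls were lost with an estimated correlation (adjusted p = 0.596, 0.33 and 0.72 unpaired, and 0.15, 0.0575 and 0.177 paired). Every pair of day 5 went the opposite way from every pair of days 2 and 3, by 0.495 against day 2 and 0.423 against day 3 (exact permutation p = 0.005 and adjusted p = 0.075 each). A common shift of abundant transcripts is argued against, since 10000 lists matched on signal had a middle mean of 0.032 over the 6 pairs of days 2 and 3 against -0.272 for the list, and 0 of them were as low. A fall of these target transcripts of the same size on every day is argued against by day 5, where the lowest pair stood at 0.047. HIF hydroxylation was not measured, so whether ascorbic acid acted on it alike on every day stays open. A difference in handling or stress at harvest stays open, because the immediate early and heat shock list was lower in 6 of 6 of these pairs, by 0.0761 to 0.199. RNA quality cannot be told apart from treatment either. At day 2 the 3' minus 5' signal of Actb was lower in the treated array of 3 of 3 pairs, by -0.22 on average against an SD of 0.232 among controls. At day 3 it differed by 0.0933 on average, against an SD of 0.0473, and from -0.01 to 0.25 over the pairs. An action of ascorbic acid limited to the first days may account for the pattern as well, and was not tested.

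Germline genes controlled by methylation were higher with ascorbic acid at day 2 as a list, by 0.295 on average, with 6 of 21 risen and 1 fallen in the paired fit and 0 called in the unpaired fit (limma). That call was lost with an estimated correlation (adjusted p = 0.596 unpaired and 0.185 paired). A lag of treated aggregates along the difference between day 0 and day 2 controls is argued against. Such a lag of all other genes gives a share of at most 0.0392 of the change in any pair. That difference also holds the change of medium, so a lag in differentiation alone was not measured. The control array with the highest 3' minus 5' signal is argued against as the only carrier, since the lowest of the other pairs stood at 0.206. This does not exclude RNA quality, because the Actb signal was lower in the treated array of all 3 pairs (-0.22 on average, -0.32 to -0.03, SD of controls 0.232), so RNA quality and treatment cannot be told apart at day 2. Whether the rise had equal size on every day cannot be decided here, because the list was taken up for its call at day 2. For the 14 members above 4 in every group, the highest of the 6 pairs of days 3 and 5 stood at 0.145 and the lowest of day 2 at 0.173. The direct test between days, which leaves the pairing out, did not pass (exact permutation p = 0.36 for day 3 and 0.245 for day 5 against day 2). Methylation was not measured on these arrays, so how it changed on any day stays open. Loss of methylation under ascorbic acid is a candidate explanation that stays open for day 2 beside RNA quality, although 1 member, Ddx4, was called lower in the paired fit.

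Probe sets without a gene symbol, which no comparison uses, also changed in the unpaired fit, and gene names are not given for them in the annotation used here. Probe set 1450943_at was higher with ascorbic acid by 1.64 at day 3 (adjusted p = 0.0395), 2.21 at day 5 (adjusted p = 0.000129) and 1.73 on average (adjusted p = 2.1e-06). At day 5 probe set 1418493_a_at was higher by 1.16 (adjusted p = 0.0428) and 1436853_a_at by 2.35 (adjusted p = 0.0133). Of 9160 such probe sets the paired fit called 59 at day 2, 1 at day 3, 15 at day 5 and 25 on average.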

How the results depend on the processing

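Settings chosen after seeing the data were the paired fit with its alternatives and the fit without replicate 3 of days 2 and 3 in both arms; all others were planned. Of the named genes, 0 reversed in any setting, but this count says little about their direction. Named genes were called genes, and those with the largest changes also had replicates without overlap or pairs of the same sign. Leaving out an array or pair could not turn the sign of these. Other probe sets of a named gene could differ in sign, as those of Dpys did at day 2. Of 16 genes named for ascorbic acid in the unpaired fit, 235 of 329 comparisons kept their call and 94 lost it. In the paired fit, 1571 of 1962 kept it for 153 genes and 391 lost it. For time, 3007 of 3294 kept it for 207 genes and 287 lost it. The position measure stayed below 0 and uncalled in every setting. Low signal limits dim genes: 12033 genes lay above the median signal of 6.13. Unless the setting itself tests fewer genes or arrays, the cause was not tested.

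Counts of genes that moved by over 1.5 times, in the order days 2, 3, 5, average and day difference where given, follow. The replicate block gave 19 genes at day 5, 12 on average, and 4 called lists at day 3. Array weights gave 1682 at day 2, 7 at day 3, 90 on average, 7 differing between days, 5130 from day 0 to 2 and 5014 from day 2 to 3. The mean of all probe sets gave 2 at day 2, 3 differing between days and 6 lists at day 3, and in the paired fit 313 at day 2, 16 at day 3 and 39 differing between days. Every probe set on its own gave 2, 1 and 31 at days 2, 3 and 5, 3 differing between days, 3835 from day 0 to 2 and 5949 from day 3 to 5, and in the paired fit 737 at day 2, 277 at day 5 and 169 differing between days. Only genes above the median signal gave 0 at day 2 (limma), 5 at day 5, 2 on average, and 3 and 4 lists at days 2 and 3, and in the paired fit 21 at day 3 and 53 differing between days. Renewed quantile normalisation gave 2 at day 2 and 8 on average. Only the arrays of the groups compared gave 2, 5 and 3 at days 2, 3 and 5, 28 on average, 4 differing between days and 198 from day 0 to 2. The replicate block within day, which is the paired fit, gave 481, 36 and 174 at days 2, 3 and 5, 353 on average, 93 differing between days, and 8, 9 and 14 lists at day 3, at day 5 and on average. Without replicate 3 of days 2 and 3 in both arms, 2 were called at day 2 and 0 differed between days. Without an intensity trend the paired fit gave 298 at day 2, 18 at day 3 and 53 differing between days, and with only the arrays of the day compared 100, 135 and 83 at days 2, 3 and 5.

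In the unpaired fit, lists called with an estimated correlation were 1 at day 2, 0 at day 3, 1 at day 5, 1 on average, 2 from day 0 to 2, 0 from day 2 to 3 and 8 from day 3 to 5. The paired fit called 1, 1, 1 and 3 at days 2, 3, 5 and on average. Unpaired, the fry test called 1, 0, 1 and 1 for ascorbic acid and 2 from day 2 to 3.

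Leaving out 1 array gave 0 to 8 genes at day 2, 0 to 1 at day 3, 1 to 54 at day 5, 1 to 12 on average, 1 to 11 differing between days, 1122 to 3713 from day 0 to 2, 258 to 1054 from day 2 to 3 and 2224 to 2964 from day 3 to 5. The position ran from -0.0543 to -0.0168. Leaving out 1 pair in the paired fit gave 89 to 1212 at day 2, 6 to 14 at day 3, 56 to 184 at day 5, 189 to 648 on average and 37 to 182 differing between days. Where an arm kept 2 arrays, its spread was taken as that of the other groups.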

Other observations

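Chosen after their values were seen are the genes and lists described here. In the paired fit Acta2 was higher by 0.66, 0.79 and 0.74 at days 2, 3 and 5, and the collagen gene Col1a2 by 0.58 ± 0.08 on average in 9 of 9 pairs (adjusted p = 0.000816, limma). These hold for the brightest probe sets. The other probe sets of Acta2, which are dim, read -0.03, 0.02 and -0.09, and -0.07, 0.05 and 0.19, and its average was not called with the mean of all probe sets (0.25, adjusted p = 0.0586). Those of Col1a2 read 0.15, 0.22 and 1.52, and -0.05, -0.13 and 0.02. The smooth muscle and matrix lists were not called on average (paired adjusted p = 0.126 and 0.6). Amino acid response genes rose in 3 of 22 cases on average in the paired fit (Cth 0.51 ± 0.09, Mthfd2 0.33 ± 0.06, Psph 0.25 ± 0.06; 8 adjusted over the list alone; adjusted p = 0.000309, and adjusted p = 0.236 with an estimated correlation). Ddx4, a germ cell gene, went against the germline list, at -0.73 at day 2 (adjusted p = 0.0159) and -0.78 at day 3 (adjusted p = 0.0382) in the paired fit.

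Day 0 replicate 1 lay 0.59 of the way from the other day 0 arrays to the day 2 controls over all genes. Its array weight was 0.214, and that of day 2 control replicate 1 was 7.61.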
